A study of Arabidopsis thaliana with 7 samples.

How the data were processed

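Transcript levels were measured on 7 Affymetrix ATH1 arrays, each hybridised with biotin-labelled target made from total RNA of whole Arabidopsis thaliana plants of the Col-0 accession at 17 days of age. The labels put 3 arrays in the wildtype group, 2 in the group of an insertion mutant of UPF1 and 2 in the group of an insertion mutant of UPF3, and number the replicates within each group. They do not say whether the replicates came from separate batches of plants, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

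The deposited table held 22810 probe sets with 1 linear signal intensity per array, made by the authors with MAS5 in GCOS per the submitters' processing notes, whose versions were not given in the sources used here. The trimmed mean of every array, without the highest and the lowest 2% of signals, was 100.01, so the arrays had been scaled to 1 common mean before deposit. MAS5 subtracts a mismatch-based background from each probe set on its own, which makes signals far below the median noisy on a log scale and makes large folds of weak probe sets depend on how low values are treated. No signal was at or below 0, and detection calls were not used here. No column of the table was left without a sample.

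Signals were taken to log2 without further normalization. The 64 control probe sets were left out, and a probe set was kept when it lay above the 40th percentile of its array on at least 2 of the 7 arrays, which removed 8016 and left 14730 tested. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), and p-values were adjusted by Benjamini-Hochberg over all tested probe sets with a threshold of 0.05. A fit of the 3 groups, with 4 residual degrees of freedom and a prior of 8.81, gave upf1 minus wildtype, upf3 minus wildtype and upf3 minus upf1. A fit of the 4 mutant arrays against the 3 wildtype arrays, with 5 residual degrees of freedom and a prior of 7.40, gave the pooled comparison. All 4 comparisons, their design and the main test were set before the data were examined. Overlaps between the mutants were set beside those of independent lists and beside 100 simulations of unchanged mutants against shared controls. The tests were tried on simulated data in which 200 of 14730 probe sets were shifted. A shift of 1 on the log2 scale was recovered for 74.7% of its probe sets in the upf1 comparison, 64.8% in upf3, 69.0% between the mutants and 78.9% in the pooled comparison, and a shift of 0.5 for 11.3%, 15.5%, 9.86% and 29.6%. Far fewer probe sets were shifted than were called in most real comparisons, and the adjusted threshold depends on that number. These shares are thus not the sensitivity in the real data. Each came from a single simulated set, with 53 and 46 of 71 probe sets recovered for a shift of 1 in upf1 and upf3. These 2 comparisons have the same design, so this gap is not read as a difference between them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

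Gene names came from the platform annotation and were updated through the Entrez identifier with the RefSeq gene table of assembly TAIR10.1, which was used only for names and for which genes are neighbours, so no coordinates are given. It paired 13513 probe sets with 1 gene, 503 with several and 8794 with none, and of the tested probe sets 7986, 295 and 6449. Probe sets with several genes or none entered the counts but were not named. No named probe set was paired with the UPF1 locus, so UPF1 was not analysed here by name. Gene models with untranslated regions were not used here.

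The genes named in the text were chosen by a rule set before the data were examined. UPF3 was always reported. For each mutant and for the pooled comparison, the rule took the 8 largest rises and the 6 largest falls among called probe sets with exactly 1 gene whose mutant and wildtype arrays did not overlap, and for upf3 minus upf1 the 5 largest each way. It also took the 4 members of each gene list with the smallest p in the pooled comparison. Genes named outside this rule are said to have been chosen after their values were seen. The gene lists numbered 40. Of these, 17 held loci written down before the data were examined, and 1 of annotated pseudogenes was fixed as a class. The 17 lists written first held 354 genes, of which 73 were named on the array. The other 22 lists were added after the annotation had been read and before any comparison was made. Some were annotated gene families taken by name, and others were written down as loci. The wider pathogen-inducible list was written as 41 loci, of which 25 were named on the array. The wider NLR, ribosomal protein and wider photosynthesis lists were written as loci as well. A gene with several probe sets was represented by the one with the highest mean. The 31 lists with at least 3 tested members were tested with limma's camera against the 7890 genes of the list tests, with a preset inter-gene correlation of 0.01 and again with the correlation estimated from the arrays, and p-values were adjusted over the 31 lists of a comparison. With so few arrays the estimated correlation was imprecise. The second p was often much larger, also where the estimated correlation lay below the preset 0.01. For the drought and cold genes in upf1, with an estimated correlation of -0.22, the unadjusted camera p went from 0.000413 to 0.0234. A larger second p is thus by itself no sign of correlated genes. Limma's fry was planned as well and asks whether list members changed, without comparing them with the other genes. Its p is given below only for the reported NMD targets. The tests can differ either way: for ribosomal proteins in upf1 camera gave an adjusted p of 0.0364 and fry one of 0.486.

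The alternatives tried were quantile normalization, centring on the 75th percentile, log2(signal + 16), no low-signal filter or one at the 60th percentile, a variance model without a trend or a robust one, the replicate number as a block, leaving out each array in turn, leaving out probe sets that can match several transcripts, fitting only the 2 groups compared, averaging both mutant contrasts and a 1.5-fold minimum. A covariate of the actin 3'/5' signal ratio, which rises as RNA degrades or labelling shortens, was added after the arrays had been seen. A dim gene could pass the low-signal filter only through the arrays where it was high, such as the 2 of a mutant. Medians with the filter at the 60th percentile can therefore be moved by this selection. In the fits without 1 array the low-signal filter was the one set on all 7 arrays, and a group left with 1 array was assumed to vary like the others.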

Results

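The series compared plants carrying a mutation in UPF1 or in UPF3 with wildtype plants to find genes regulated by nonsense-mediated mRNA decay (NMD). Both proteins act in this pathway, which removes transcripts with an early stop codon, a long 3' untranslated region or an upstream open reading frame (uORF). All plants were grown on soil at 22 °C in continuous light after 3 days of stratification at 4 °C, and whole plants were collected at 17 days. There were 3 wildtype, 2 upf1 and 2 upf3 arrays. Median signal ran from 37.1 to 41.2 over the 7 arrays. The mean correlation of an array with the others of its group ran from r = 0.957 to 0.968 across probe sets. The leading principal component, with 58.3% of the variance, placed wildtype between -47.8 and -42.1, upf3 at 45.9 and 53.2, and both upf1 arrays in between. Of 3 measures of RNA quality 1 moved with the groups. The GAPDH 3'/5' signal ratio was 0.936 to 0.949 on the wildtype arrays, 1.07 and 1.11 on upf1 and 1.09 and 1.15 on upf3. The actin 3'/5' ratio was 1.91, 1.86 and 3.26 in wildtype, 4.16 and 2.38 in upf1 and 4.85 and 2.86 in upf3, so that its groups overlapped. The ubiquitin 3'/5' ratio was 1.32, 1.104 and 1.34 in wildtype, 1.51 and 0.948 in upf1 and 1.14 and 1.16 in upf3. The GAPDH ratio thus moved with every difference between mutants and wildtype given here. The share of probe sets with a signal above 1000 was 2.63% to 2.69% in wildtype, 2.48% and 2.51% in upf1 and 2.27% and 2.04% in upf3.

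The mutated gene UPF3 (AT1G33980) was lower on both upf3 arrays, at signals of 45.6 and 45.5, than on the wildtype arrays, at 114, 116 and 109. The difference was -1.31 on the log2 scale (SE 0.16, adjusted p = 5.68e-05). On the upf1 arrays its signal was 186 and 159, a rise of 0.61 (SE 0.16, adjusted p = 0.0229). The position of the insertion relative to the probes was not given in the sources used here, and probes beyond an insertion would not check the labels. The rise in upf1 was no longer called without wildtype replicate 1 (0.61, adjusted p = 0.0531), wildtype replicate 2 (0.63, adjusted p = 0.0596), upf1 replicate 1 (0.49, adjusted p = 0.162) or upf1 replicate 2 (0.72, adjusted p = 0.0545).

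**Figure D1:**
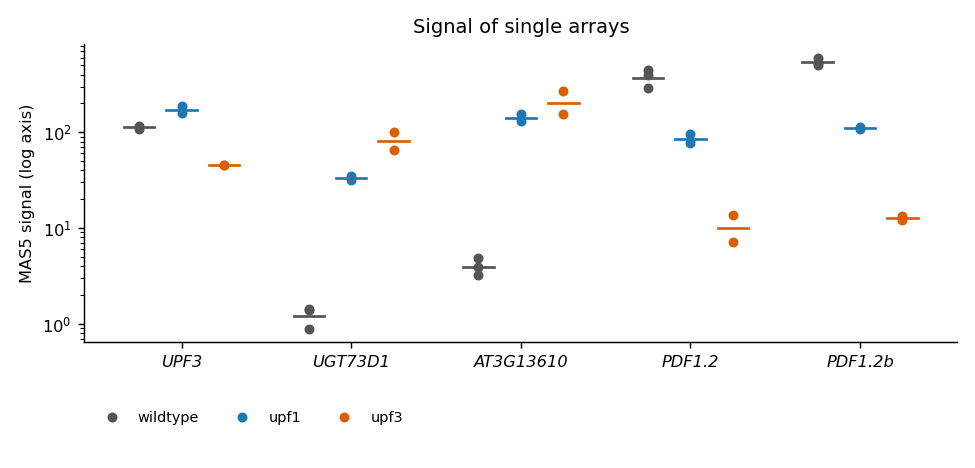
MAS5 signal (log axis) of 5 named genes on each of the 7 arrays, with points for arrays and bars for the geometric mean of a group (wildtype n = 3, upf1 n = 2, upf3 n = 2). UPF3 was lowest in upf3 and highest in upf1, UGT73D1 and AT3G13610 were higher and both PDF1.2 genes lower in each mutant than in wildtype.

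In upf1 the largest rises on the log2 scale were those of genes with weak signals in wildtype, an order that depended on how low signals are treated. AT3G13610, the feruloyl-CoA hydroxylase of scopoletin synthesis, went from a signal of 4.00 ± 0.785 (SD, n = 3) in wildtype to 142 ± 15.8 (n = 2), a log2 change of 5.16 (SE 0.31, adjusted p = 3.17e-06). The UDP-glycosyltransferase gene UGT73D1 (AT3G53150) went from 1.22 ± 0.293 to 33.1 ± 1.97, a change of 4.79 (SE 0.77, adjusted p = 0.00131). AT1G59930 rose by 4.86, AT2G44240 by 3.72 and AT1G26420, a berberine bridge enzyme-like gene, by 4.21. Rises of 3.94, 3.86 and 3.79 were called for AT3G28580, an AAA-type ATPase, AT4G17470 and AT3G57950. The largest log2 falls were those of the transcription factor gene BZIP61 (AT3G58120), from 51.3 ± 18.5 to 2.44 ± 1.22 (log2 change -4.43, SE 0.82, adjusted p = 0.00303), of the cupredoxin gene AT1G72230 (-4.01) and of AT1G11850 (-3.49). They were followed by falls of AT2G16750 (-3.41), the glutaredoxin gene AT3G62950 (-3.12) and AT4G01410 (-3.04). Most of these genes had 1 side of the comparison near the floor of the array. With 16 added to every signal the changes shrank to 2.98 for AT3G13610, 1.51 for UGT73D1, 3.01 for AT1G59930, 2.596 for AT2G44240, 1.56 for AT1G26420, 1.099 for AT3G28580, 1.35 for AT4G17470 and 0.96 for AT3G57950. The falls shrank to -1.83 for BZIP61, -1.54 for AT1G72230, -2.05 for AT1G11850, -1.12 for AT2G16750, -1.19 for AT3G62950 and -1.24 for AT4G01410. Ranked with 16 added, 3 of the 8 rises and 2 of the 6 falls stayed among the largest, and PDF1.2b (-2.14) passed all 6 of these falls.

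Over all probe sets, 1965 were called in upf1, 1170 higher and 795 lower, and 538 and 233 of them differed at least 2-fold. Without upf1 replicate 2 the count was 952, and it was 1190 without the intensity trend in the variance. Several of the calls above ended without 1 array. Apart from AT2G16750 without upf1 replicate 1 (-1.81) and AT3G62950 without upf1 replicate 2 (-1.67), the sizes of these changes stayed similar. The calls of AT3G28580, AT4G17470 and AT3G57950 ended without upf1 replicate 1 (adjusted p = 0.27, 0.137 and 0.207), upf1 replicate 2 (0.142, 0.0996 and 0.121) or upf3 replicate 1 (0.142, 0.0544 and 0.139). Those of AT3G28580 and AT3G57950 also ended without upf3 replicate 2 (0.128 and 0.182). The upf3 arrays enter here through the shared spread. The call of AT1G26420 ended without upf1 replicate 2 (0.0608), and that of AT3G62950 without upf1 replicate 2 (0.0692) or wildtype replicate 2 (0.0694). AT2G16750 and AT4G01410 lost theirs without wildtype replicate 1 (0.0722 and 0.0859), 2 (0.107 and 0.142) or 3 (0.11 and 0.0651) and upf1 replicate 1 (0.136 and 0.115). AT2G16750 also lost its call without upf3 replicate 1 (0.0581) and AT4G01410 without upf1 replicate 2 (0.0537). Fitted on the wildtype and upf1 arrays alone, 5 of the 8 largest rises were not called: UGT73D1 (adjusted p = 0.116), AT1G26420 (0.0545), AT3G28580 (0.239), AT4G17470 (0.0836) and AT3G57950 (0.351). AT3G28580 and AT3G57950 also lost their calls after quantile normalization (0.0725 and 0.0602) and with the actin covariate (0.0548 and 0.0668), and AT2G16750 with that covariate (0.0796) and without the intensity trend (0.0527). With the covariate these changes were 4.201, 3.58 and -3.14, so their sizes stayed similar.

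In upf3, 7 of the 8 genes with the largest log2 rises were also among the 8 largest in upf1, but 4 of 8 when both were ranked with 16 added to every signal. AT1G59930 rose by 6.21 (SE 0.47, adjusted p = 1.8e-06), UGT73D1 by 6.09 (SE 0.77, adjusted p = 8.86e-05). AT3G13610 rose by 5.68 to a signal of 211 ± 80.7 (n = 2), AT1G26420 by 5.46 and AT2G44240 by 4.93. AT3G57950 rose by 5.60, AT2G19970, of the family of pathogenesis-related protein 1, by 5.40 and AT3G28580 by 4.71. The largest falls were those of the jasmonate- and ethylene-induced plant defensin genes. PDF1.2b (AT2G26020) went from 544 ± 52.1 (n = 3) to 12.9 ± 0.876 (n = 2), a change of -5.40 (SE 0.16, adjusted p = 6.81e-10). PDF1.2 (AT5G44420) went from 378 ± 81.4 to 10.5 ± 4.65, a change of -5.22 (SE 0.27, adjusted p = 2.18e-07). AT5G15780 (-4.27) and the copper amine oxidase gene AT1G31690 (-3.42) fell as well, as did AT3G55710 (-4.65) and AT3G06160 (-3.82). With 16 added to every signal the changes were 4.28 for AT1G59930, 3.73 for AT2G44240, 3.46 for AT3G13610, 2.54 for AT1G26420, 2.51 for UGT73D1, 2.496 for AT2G19970, 2.16 for AT3G57950 and 1.58 for AT3G28580. They were -4.27 for PDF1.2b, -3.88 for PDF1.2, -2.23 for AT5G15780, -2.22 for AT1G31690, -1.41 for AT3G55710 and -1.13 for AT3G06160. Ranked in this way, 3 of the 8 rises and 2 of the 6 falls stayed among the largest.

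In all, 4564 probe sets were called in upf3, 2515 higher and 2049 lower, of which 1148 and 606 differed at least 2-fold. Centring the arrays on their 75th percentile moved the median of all probe sets from 0.02 to -0.10 and turned the split into 1982 higher and 2707 lower. The balance of rises and falls thus depended on the scaling. The count was 2525 without upf3 replicate 2. Without that array the calls of AT3G57950 (adjusted p = 0.126), AT2G19970 (0.0689), AT3G28580 (0.119) and AT3G55710 (0.0717) ended. AT3G28580 was also lost without upf3 replicate 1 (0.133). AT3G55710 was lost without wildtype replicate 1 (0.0784), 2 (0.0636) or 3 (0.0983) and AT3G06160 without wildtype replicate 2 (0.0638) or 3 (0.0613). In these fits the changes kept 78.6% to 105% of their size.

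With both mutants pooled against wildtype, the reported NMD targets on the array were led by 2 clear rises. AT1G36730, which encodes a translation initiation factor eIF5, went from 214 ± 28.9 (n = 3) in wildtype to 612 ± 18.8 (n = 2) in upf1 and 1118 ± 30.5 (n = 2) in upf3, a pooled change of 1.96 (SE 0.23, adjusted p = 0.00012). The protein kinase gene AT5G45430 went from 172 ± 6.11 to 422 ± 71.7 and 784 ± 32.8, a pooled change of 1.74 (SE 0.23, adjusted p = 0.000288). AT2G45670 was not called (-0.21, adjusted p = 0.479), nor was UPF3 (-0.35, adjusted p = 0.6), which moved in opposite directions in the mutants. Of the 6 tested targets 2 rose and 0 fell, also when adjusted over the list alone. The list's median of 0.03 did not pass the test (adjusted p = 0.293, and 0.496 with an estimated correlation). It was -0.06 after quantile normalization and -0.05 after centring on the 75th percentile. In upf1 the same list had 3 rises and 0 falls, with UPF3 as the third member called, and a median of 0.31 (adjusted p = 0.0178, and 0.209 with an estimated correlation). That list call ended without upf1 replicate 2 (adjusted p = 0.0556). In upf3 the list had 2 rises and 1 fall, that of the mutated UPF3, and a median of 0.07 (adjusted p = 0.42, and 0.556 with an estimated correlation). The fry test, which makes no comparison with other genes, gave this list an adjusted p of 0.00509 in upf1 and 0.00294 in upf3. The 5 tested factors of NMD and of the exon junction complex had 0 members called in either direction, also adjusted over the list alone, with a median of -0.02 and a mean of 0.01 (adjusted p = 0.961, and 0.968 with an estimated correlation).

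Of 16 tested genes with a conserved peptide uORF 8 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.61 (adjusted p = 0.00156, but 0.288 with an estimated correlation). AT5G15950, an S-adenosylmethionine decarboxylase gene of polyamine synthesis, rose by 1.13 (SE 0.15, adjusted p = 0.000234), AT3G53670 by 1.32 and AT1G70780 by 0.68. AT1G36730 is also a member. In upf1, 7 members rose and 0 fell (8 and 0 adjusted over the list alone, median 0.44, adjusted p = 0.000375, and 0.217 with an estimated correlation). In upf3, 9 rose and 0 fell (9 and 1 adjusted over the list alone, median 0.78, adjusted p = 0.000272, and 0.257 with an estimated correlation). The 3 tested splicing regulators, among them ATU2AF65A (-0.31, adjusted p = 0.142), had 0 calls, also adjusted over the list alone (median -0.29, adjusted p = 0.389, and 0.598 with an estimated correlation).

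All 3 tested genes of the salicylic acid and pathogen response rose, also when adjusted over the list alone: the glutaredoxin gene GRX480 by 2.04 (SE 0.24, adjusted p = 0.000137), the transcription factor gene WRKY53 by 1.85 and SAG101, which encodes a partner of the immune regulator EDS1, by 1.51. Their median was 1.85 (adjusted p = 0.000723, and 0.288 with an estimated correlation). Among the wider set of 24 pathogen-inducible genes, which holds these 3, 23 rose and 0 fell, with a median of 1.76 (adjusted p = 9.88e-22, and 0.288 with an estimated correlation). In upf1 the median was 1.51 with 23 rises (adjusted p = 6.3e-25, and 0.0489 with an estimated correlation). This was the 1 list call that held with an estimated correlation in any of the 4 comparisons. In upf3 the median was 1.94 with 23 rises (adjusted p = 9.24e-21, and 0.0693 with an estimated correlation). The chitinase gene CHI (AT2G43570) went from a signal of 278 ± 57.8 to 1233 ± 334 in upf1 and 1783 ± 576 in upf3, a pooled change of 2.40 (SE 0.23, adjusted p = 3.05e-05). The EF-hand gene AT3G47480 rose by 2.25, AT5G52760 by 1.99 and AT3G60420 by 1.77. On the same arrays the GAPDH 3'/5' ratio was higher in all 4 mutants than in the 3 wildtype samples.

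Of the 7 tested receptor genes of the NLR class, intracellular immune receptors, in the list written first, 3 rose and 0 fell (3 and 0 adjusted over the list alone): AT1G72890 by 1.25, AT1G66090 by 0.90 and CSA1 by 0.76 (adjusted p = 0.00739, but 0.59 with an adjusted p of 0.0764 with the actin ratio as a covariate). AT4G19510 stood at 0.52 (adjusted p = 0.0977). The list's median was 0.52 (adjusted p = 0.0169, and 0.288 with an estimated correlation), and its call ended with the filter at the 60th percentile (median 0.76, adjusted p = 0.0612). The wider set of 60 NLR loci, which holds these 7, had 19 rises and 0 falls (median 0.40, adjusted p = 9.89e-05, and 0.288 with an estimated correlation). AT1G57630 rose by 2.58 (SE 0.14, adjusted p = 1.75e-06), from 44.0 ± 5.47 to 255 ± 2.89 in upf1 and 269 ± 38.4 in upf3. AT5G58120 rose by 1.65, AT5G45510 by 0.93 and AT2G20142 by 1.27 in upf1 and 1.53 in upf3. The wider set's median was 0.83 with the filter at the 60th percentile and 0.26 with 16 added to every signal. Loci high only in mutants can pass that filter, so the selection itself can raise the 0.83.

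Of the genes of jasmonate- and ethylene-dependent defence, PDF1.2b fell by 3.84 (SE 0.69, adjusted p = 0.00189) and PDF1.2 by 3.67 (SE 0.71, adjusted p = 0.00309). The probe set of PDF1.2b is of a kind that can match several transcripts, so its fall may not be separate from that of PDF1.2. The thionin gene THI2.1 was not called (-0.01, adjusted p = 0.992). Thus 2 of the 3 tested members fell and 0 rose, also adjusted over the list alone (median -3.67, adjusted p = 0.0476, and 0.288 with an estimated correlation). This list call ended without wildtype replicate 1 (adjusted p = 0.0605) or wildtype replicate 3 (0.0647), under quantile normalization (0.085) or centring on the 75th percentile (0.0793), without the intensity trend (0.0946) and with the actin covariate (0.0625), with medians from -3.86 to -3.23. In the pooled fit the difference between the mutants enters the spread. Against wildtype the jasmonate and ethylene list had a median of -2.12 in upf1 (adjusted p = 0.000645, and 0.209 with an estimated correlation). In upf3 it had one of -5.22 (adjusted p = 0.00104, and 0.257 with an estimated correlation). Neither of these calls ended under another normalization or variance model. Of the 7 tested defensin and LCR genes, which include PDF1.2b and PDF1.2, 4 fell and 0 rose (median -0.56, adjusted p = 0.0115, and 0.288 with an estimated correlation). Among them LCR69 went from 1360 ± 215 to 633 ± 75.3 in upf1 and 525 ± 1.90 in upf3 (pooled change -1.23, adjusted p = 0.00016). LCR68 (-0.56) lost its call without wildtype replicate 1 (adjusted p = 0.113) or 2 (0.0709) or without the intensity trend (0.0611). In upf1 the median of the defensin and LCR genes was -0.56, and -0.31 without probe sets of the kind of that of PDF1.2b.

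Of 4 tested genes of the unfolded protein response 3 rose and 0 fell (4 and 0 adjusted over the list alone): the endoplasmic reticulum chaperone gene ATERDJ3B by 1.01 (SE 0.12, adjusted p = 0.000147), the transcription factor gene BZIP60 by 1.01 and the calnexin gene AT5G07340 by 0.86. CRT1b stood at 0.36 (adjusted p = 0.0716). The median was 0.93 (adjusted p = 0.0028, and 0.288 with an estimated correlation). Of the 3 tested drought and cold genes 2 fell and 0 rose (3 and 0 adjusted over the list alone), the dehydrin gene COR47 with a change of -0.93 (SE 0.16, adjusted p = 0.00134) and COR15B with -1.02. COR15A stood at -0.35 (adjusted p = 0.087). Their median was -0.93 (adjusted p = 0.0118, and 0.288 with an estimated correlation). The only tested heat shock gene, AT3G09440, stood at -0.02 (adjusted p = 0.93). PYK10, the beta-glucosidase of root endoplasmic reticulum bodies, rose by 1.97 (SE 0.21, adjusted p = 6.87e-05). The other tested root marker, EXPA18, was not called (0.02, adjusted p = 0.984), so 1 of 2 rose, also adjusted over the list alone. GI, the only tested member of the flowering time and of the clock list, was not called (-0.39, adjusted p = 0.074) but counted as lower when adjusted over either list alone. The 5 reference genes, including PEX4 (-0.14, adjusted p = 0.485), had 0 calls, also adjusted over the list alone (median -0.01, adjusted p = 0.772). No member of the senescence list or of the floral organ and pollen list was tested.

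**Figure D2:**
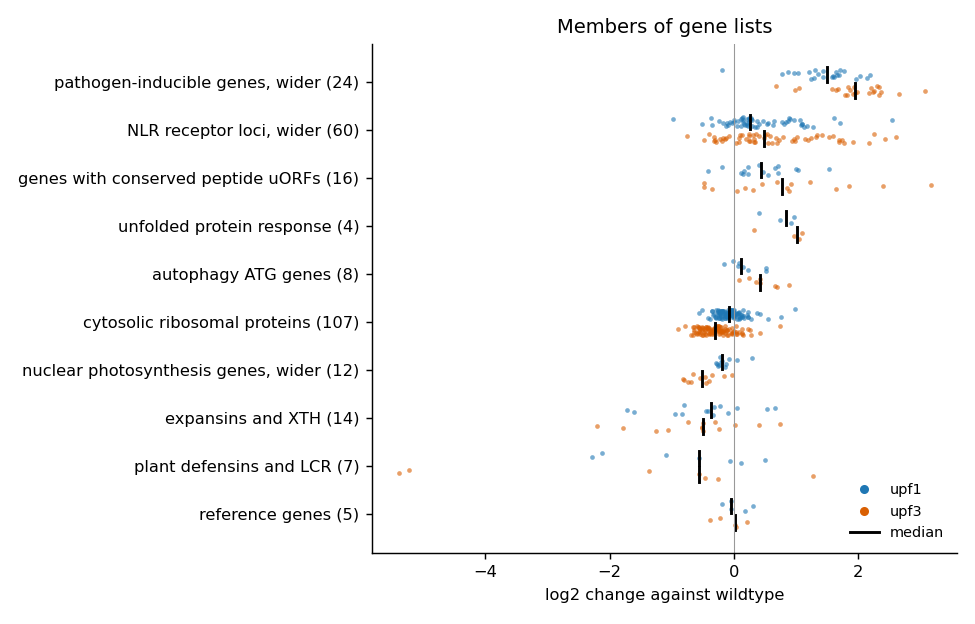
Log2 change against wildtype in upf1 and upf3 of the tested members of 10 gene lists, with 1 point per gene, a black tick at each median and the number of members in parentheses. The 24 pathogen-inducible genes had medians of 1.51 and 1.94, and the 5 reference genes lay around 0.

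Pooled, 3507 probe sets were called, 2005 higher and 1502 lower, of which 839 and 347 differed at least 2-fold. AT1G59930 (5.53), UGT73D1 (5.44), AT3G13610 (5.42), AT1G26420 (4.84), AT3G57950 (4.69), AT3G28580 (4.33), AT2G44240 (4.32) and AT4G17470 (3.90) had the largest log2 rises. PDF1.2b, PDF1.2, AT3G55710 (-3.67), BZIP61 (-3.49), AT3G06840 (-3.44) and AT5G15780 (-3.28) had the largest log2 falls. Near the floor of the array such sizes and their order depend on how low signals are treated. With 16 added to every signal these rises became, in the same order, 3.64, 2.01, 3.22, 2.05, 1.56, 1.34, 3.16 and 1.38, so that several fell below the 2.21 of AT1G57630. The falls became -3.20, -2.91, -1.21, -1.57, -1.12 and -1.90. Ranked in this way, 3 of the 8 rises and 2 of the 6 falls stayed among the largest. Centred on the 75th percentile, the median of all probe sets moved from 0.01 to -0.07 and the split became 1647 higher and 1916 lower. The count was 2294 without wildtype replicate 1, 2278 without wildtype replicate 2 and 2055 with the actin ratio as a covariate. Calls ended for BZIP61 without wildtype replicate 1 (adjusted p = 0.0565), for AT3G57950 without upf3 replicate 2 (0.0702), and for AT3G28580 without upf3 replicate 1 (0.0506). They also ended for AT3G55710 without wildtype replicate 1 (0.154), 2 (0.121) or 3 (0.174), and for AT3G06840 without these (0.11, 0.241 and 0.19) or upf3 replicate 2 (0.0509). With the actin covariate the calls of AT3G55710 (-4.69, adjusted p = 0.0526) and AT3G06840 (-3.23, adjusted p = 0.162) ended although the changes stayed large, and that of AT3G06840 also after quantile normalization (0.0666). Over all named genes whose pooled call ended without 1 array, the change kept 77.03% to 112% of its size.

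Both mutants shared most of the genes called in upf1. In the same direction in both, 1086 probe sets were higher and 674 lower, where independent lists of these sizes would share 200 and 111. The probe set of UPF3 was the 1 called in opposite directions. Simulated unchanged mutants against shared controls gave a mean of 0.01 probe sets called in the same direction and 0 in opposite directions. The simulated noise was independent between probe sets, so deviations shared by many genes on an array were left out and the simulated numbers may be too low. Across probe sets, which are not independent replicates, the log2 changes correlated at r = 0.836 against 0.403 in the simulations, with a covariance of 0.389 against 0.0316. The 3 controls were too few for 2 sets of at least 2 arrays, so part of the excess over independent lists may come from the shared controls. The 1760 shared calls fell to 1157 without upf1 replicate 1, 884 without upf1 replicate 2 and 1085 without the intensity trend, and the correlation was 0.626 without the low-signal filter.

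**Figure D3:**
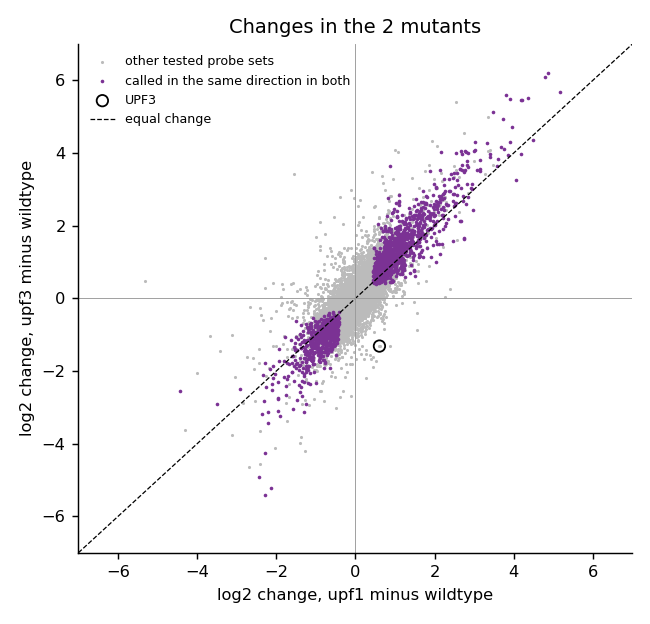
Log2 change in upf3 against log2 change in upf1 for every tested probe set, with those called in the same direction in both in purple, UPF3 circled and a dashed line of equal change. The changes correlated at r = 0.836, and UPF3 was the only probe set called in opposite directions.

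Changes were larger in upf3 than in upf1. For the 2005 probe sets higher in the pooled comparison the median change was 0.74 in upf1 and 1.02 in upf3, and 84.3% of them changed more in upf3. For the 1502 lower ones the medians were -0.59 and -0.86, with 81.8% changing more in upf3. On single arrays the median of the higher set was 0.730 and 0.756 in upf1 and 0.981 and 1.08 in upf3. The slope of the leading principal axis of upf3 against upf1 changes, which is not a regression slope, was 1.41, against a simulated mean of 1.00. Few of these probe sets passed the test of the difference itself, 73 of the higher and 65 of the lower set, of which 72 and 63 were further from wildtype in upf3.

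Tested directly, upf3 differed from upf1 in both PDF1.2 genes and in some strongly induced genes. PDF1.2b was lower in upf3, with a difference of -3.11 (SE 0.17, adjusted p = 1.09e-06), and so was PDF1.2, with -3.10 (SE 0.29, adjusted p = 0.000238). AT3G53400 went from 86.3 ± 18.9 in wildtype to 161 ± 56.9 in upf1 and 1067 ± 179 in upf3 (difference 2.76, SE 0.25, adjusted p = 0.00018). CPUORF47 (AT5G03190), a gene with a conserved peptide uORF, went from 59.0 ± 19.7 to 93.2 ± 5.87 and 520 ± 124 (difference 2.46, SE 0.26, adjusted p = 0.000589). The linker histone gene HIS1-3 (2.48), the osmotin gene OSM34 (2.02) and AT1G78110 (2.25) were higher in upf3, and AT3G23550 (-2.25), AT5G61300 (-2.07) and UPF3 (-1.92, SE 0.17, adjusted p = 0.00018) lower. With 16 added to every signal the differences were 2.64 for AT3G53400, 2.28 for CPUORF47, 1.79 for HIS1-3, 1.47 for OSM34 and 1.06 for AT1G78110. They were -2.14 for PDF1.2b and -1.95 for PDF1.2, whose signals in upf3 were near the floor, and -1.30 for AT3G23550, -1.102 for AT5G61300 and -1.61 for UPF3. Without the intensity trend the calls of CPUORF47 (adjusted p = 0.0607), HIS1-3 (0.0845), OSM34 (0.104), AT3G23550 (0.0607) and AT5G61300 (0.0607) ended. Without the low-signal filter those of AT1G78110 (0.0647) and AT5G61300 (0.0675) ended, and AT1G78110 had an adjusted p of 0.0776 with only the 2 groups fitted. The NMD targets AT1G36730 (0.87, adjusted p = 0.0198) and AT5G45430 (0.90, adjusted p = 0.0174) were higher in upf3 than in upf1.

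Between the mutants 226 probe sets were called, 124 higher and 102 lower in upf3. The split turned with the scaling, to 93 higher and 127 lower with centring on the 75th percentile and 113 and 115 after quantile normalization, and it was 200 and 77 with only the 2 groups fitted. The count was fragile. It was 144 without wildtype replicate 1, 120 without wildtype replicate 2, 90 and 48 without upf1 replicates 1 and 2, and 124 and 30 without upf3 replicates 1 and 2. It was 16 without the intensity trend, 96 without the low-signal filter, 344 with 16 added to every signal and 550 with the actin covariate. Calls ended for HIS1-3 without upf1 replicate 2 (adjusted p = 0.065), upf3 replicate 1 (0.0734) or upf3 replicate 2 (0.154). The call of OSM34 ended without upf1 replicates 1 (0.0676) and 2 (0.0956) and upf3 replicates 1 (0.0656) and 2 (0.245). AT1G78110 and AT5G61300 lost theirs without wildtype replicate 2 (0.0833 and 0.0545), upf1 replicates 1 (0.0926 and 0.179) and 2 (0.0996 and 0.111) and upf3 replicates 1 (0.193 and 0.0787) and 2 (0.258 and 0.175). AT1G78110 also lost its call without wildtype replicate 1 (0.0512), and AT3G23550 without upf1 replicates 1 (0.0775) and 2 (0.0923) and upf3 replicate 2 (0.121). The differences kept 85.2% to 113% of their size in these fits.

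Of 107 cytosolic ribosomal protein genes 37 fell and 1 rose in upf3 (41 and 1 adjusted over the list alone, and 17 and 2 after quantile normalization), with a median of -0.31 (adjusted p = 2.36e-08, and 0.393 with an estimated correlation). In the pooled comparison 11 fell and 1 rose, but 0 and 0 adjusted over the list alone (median -0.20, adjusted p = 7.17e-05, and 0.598 with an estimated correlation). PGY1 went from 1311 ± 143 to 888 ± 75.6 in upf3 (-0.56, adjusted p = 0.0132), AT2G44120 changed by -0.65 and AT5G52650 by -0.64 there, while AT5G39850 rose by 0.74. Of 12 nuclear photosynthesis genes 8 fell and 0 rose in upf3 (median -0.51, adjusted p = 0.000263, and 0.424 with an estimated correlation). Among them were the phosphoribulokinase gene PRK, from 4373 ± 198 to 2497 ± 301 (-0.81, SE 0.15, adjusted p = 0.00112), the antenna protein genes LHCB4.1 (-0.74) and LHCB4.3 (-0.54) and the photosystem I gene PSAN (-0.69). After quantile normalization the medians in upf3 were -0.14 and -0.17, and the photosynthesis call ended (adjusted p = 0.225). Pooled, 1 photosynthesis gene fell and 0 rose (median -0.38, adjusted p = 0.00701, and 0.598 with an estimated correlation). This gene, LHCB4.3 (-0.41, adjusted p = 0.0431), lost its call without wildtype replicates 1 (0.0807), 2 (0.113) and 3 (0.142) and upf3 replicates 1 (0.104) and 2 (0.0769), after quantile normalization (-0.21, adjusted p = 0.188), without the low-signal filter (0.0744), without the intensity trend (0.0838) and with the actin covariate (-0.49, adjusted p = 0.076). Both pooled list calls ended after quantile normalization (adjusted p = 0.411 and 0.534), and the pooled ribosomal falls then numbered 4. Without upf3 replicate 2 they numbered 5, with a median of -0.13. The smaller list of light harvesting and carbon fixation genes, whose 3 tested members LHCB4.1, LHCB4.2 and RCA are among the 12, had 0 pooled calls, or 1 fall adjusted over the list alone (median -0.24, adjusted p = 0.454, and 0.703 with an estimated correlation). Its median was 0.06 after quantile normalization. These genes are among the brightest on the array, whose share of signals above 1000 was lowest in upf3.

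For annotated pseudogenes, whose transcripts often carry early stop codons, no difference from other genes was found in the share that rose. They were dimmer, with a mean log2 signal of 4.57 against 6.41 for other genes. Of 73 tested pseudogenes 8.22% were higher in upf1 against 6.88% of the other 7817 genes (Fisher's exact test, two-sided p = 0.639), 16.4% in upf3 against 16.3% (p = 1) and 12.3% in the pooled comparison against 13.0% (p = 1). All 3 adjusted p were 1. Pooled, 9 rose and 1 fell, with a median of 0.01 (adjusted p = 0.489), which was -0.08 after centring on the 75th percentile. In upf3 the median was 0.03 (adjusted p = 0.468), but 1.64 (adjusted p = 0.00952) with the filter at the 60th percentile, which leaves fewer of them. A dim pseudogene can pass that filter through the 2 upf3 arrays alone, so the selection itself can raise this median. AT3G48650 rose the most among those named, from 26.9 ± 1.70 to 123 ± 30.01 in upf1 and 440 ± 50.4 in upf3 (pooled change 3.10, SE 0.43, adjusted p = 0.000396). AT5G55420 rose by 1.43, AT2G24160 by 1.33 (1.17 with an adjusted p of 0.0707 with the actin covariate) and AT4G14610 by 1.06.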

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

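The count over other splits of the arrays and the medians on single arrays were chosen as tests only after the results had been seen; the other tests here were set beforehand, except that a bound was counted as passed only when exceeded by more than the spread over the fits without 1 array, a condition added after the slopes and the ribosomal medians had been seen. The test of single arrays was likewise held, after the slopes had been seen, to the bound that the explanation needs and not to the stricter bound set beforehand, which the lowest slope passed by less than the spread. For the matched lists of the ribosomal protein genes the results with and without the added condition are given.

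The first pattern is the number of probe sets that differed between the pooled mutants and wildtype, 3507 of 14730. Chance assignment of the arrays is argued against, since 1 of the 35 splits of the 7 arrays into 4 and 3 gave as many calls, the real one, and the highest other split gave 1184. RNA integrity, read from the actin 3'/5' ratio, is argued against as the whole cause, since the median size of the called changes kept 99.9% of its value with the ratio as a covariate (0.79 with it and without it), although the median SE rose from 0.18 to 0.21 and the count of calls went to 2055. The GAPDH 3'/5' ratio separates all mutant arrays from all wildtype arrays, so an adjustment would rest on its small differences within groups and was not made, and a quality difference of the kind it measures stays open beside the mutations themselves, which were not tested apart from it.

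The second pattern is that changes were larger in upf3 than in upf1, with a slope of the leading principal axis of 1.41. The authors' scaling and the actin ratio are argued against, since the slope was 1.38 after quantile normalization and 1.39 with the ratio as a covariate, with an SD of 0.0825 over the fits without 1 array. A single array is argued against as the whole cause, since the slope ran from 1.25 without upf1 replicate 1 to 1.53 over the fits without 1 array, and both upf3 arrays lay past both upf1 arrays. The median of the higher set was 0.981 and 1.08 on the upf3 arrays against 0.730 and 0.756 on the upf1 arrays, and that of the lower set -0.815 and -0.892 against -0.585 and -0.624. A stronger loss of function in upf3 than in upf1 stays among the open explanations, as untested.

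The third pattern is the fall of ribosomal protein and photosynthesis genes in upf3. Of 20 equal bins of named genes by signal, the brightest had a median change of -0.26 there and the next -0.12. Compression, a fall of bright signals in general, could give such values. The list members were not left out of the bins or of the genes drawn for matched lists, so their own fall can lower both. For the 107 ribosomal protein genes the bound set beforehand was passed. Of 10000 random lists matched on mean signal 0.38% had a lower median than -0.31. In the fits without 1 array, each with its own matched lists, 0.21% to 1.56% were lower. Without wildtype replicate 2, for example, the median was -0.288 against a lower bound of -0.279. The ribosomal protein genes had an estimated inter-gene correlation of 0.21, whereas the lists were drawn gene by gene. Medians of drawn lists may therefore vary less than that of genes moving together. Compression thus cannot be told apart for these genes by this test. The condition added later was not met. With all arrays the median passed the middle 95% of the lists, from -0.27 to -0.06, by less than its SD of 0.0412 over those fits. For the 12 photosynthesis genes compression cannot be told apart, since 6.45% of matched lists had a lower median than -0.51. The middle 95% ran from -0.58 to 0.07, and the SD of the median was 0.0832 over the fits without 1 array. The authors' scaling cannot be told apart for the ribosomal genes, whose median was -0.14 after quantile normalization. The UPF3 mutation stays among the open explanations, as untested.

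A test of the difference between both mutant effects, upf3 minus upf1, singled out the following. UPF3 differed by -1.92, PDF1.2b by -3.11, PDF1.2 by -3.10, AT3G53400 by 2.76, HIS1-3 by 2.48, CPUORF47 by 2.46, AT1G78110 by 2.25, OSM34 by 2.02, AT3G23550 by -2.25 and AT5G61300 by -2.07 on the log2 scale. The NMD targets AT1G36730 and AT5G45430 differed by 0.87 and 0.90, and the pseudogenes AT3G48650 and AT2G24160 by 1.86 and 1.15. Among gene lists, medians of the difference passed the test with a preset correlation for NMD and exon junction complex factors (-0.18, a list of 5 that holds the mutated UPF3, its 1 called member), conserved peptide uORF genes (0.13), the salicylic acid response (0.65), jasmonate and ethylene defence (-3.10, and -1.95 with 16 added to every signal), the wider NLR set (0.17), the wider pathogen-inducible set (0.47), ribosomal proteins (-0.21), the 12 photosynthesis genes (-0.32), autophagy genes (0.28) and defensins (-0.37). With an estimated correlation 0 of these 10 lists passed, with adjusted p from 0.312 to 0.443. The autophagy median lost its call without upf1 replicate 2 (adjusted p = 0.0821) or upf3 replicate 1 (0.107), the wider NLR median without the same arrays (0.0656 and 0.055) and the uORF median without upf3 replicate 1 (0.134). The median of the NMD and exon junction complex factors lost it without upf1 replicates 1 (0.0675) and 2 (0.0656) and upf3 replicate 1 (0.177), with the filter at the 60th percentile (0.0525), without the intensity trend (0.0665) and with the actin covariate (0.0792). Other settings also moved the size of medians that stayed called: after quantile normalization the uORF median was 0.23 and the photosynthesis median -0.15, and with centring on the 75th percentile the uORF median was 0.067 and the wider NLR median 0.11. Among single arrays, the uORF median was 0.062 without upf1 replicate 2 and 0.28 without upf3 replicate 2, the ribosomal median -0.13 without upf1 replicate 1, -0.32 without upf3 replicate 1 and -0.13 without upf3 replicate 2, the photosynthesis median -0.56 and -0.15 without upf3 replicates 1 and 2, and the defensin median -0.16 without upf1 replicate 1.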

How the results depend on the processing

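The covariate of the actin ratio, and the alternatives for the correlation of both mutants' changes, were added after the data had been seen. Over the alternatives, counts of called probe sets stayed within 1.5 times of the reported count in 58 of 76 instances. List medians kept their side of the threshold, and their direction where called, in 2026 of 2100. Named genes did so in 2753 of 2983, with 210 calls of named genes lost, 20 gained and 0 reversed. Uncalled values that changed sign, in 86 instances for lists and 30 for named genes, are counted among those kept. Of 128 calls of named genes the actin covariate ended 27, the replicate block 21, a variance without trend 13, quantile normalization 8, no low-signal filter 6 and the offset of 16 ended 0. Single arrays ended 10 to 23. Fitting only the 2 groups compared ended 6 of 40. Signals near the floor limit large folds: 33 of 143 named probe sets had 1 side below 23.4, the mean 40th percentile. Unless the construction of a setting says otherwise (fewer arrays, fewer probe sets, fewer degrees of freedom), the cause was not tested.

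Counts in upf1 went to 1190 without the intensity trend and to 952 to 1908 without single arrays, in upf3 to 2525 to 4657, between the mutants to 344 with 16 added, 96 without a filter, 16 without the trend, 550 with the actin covariate and 30 to 308 without single arrays, and in the pooled comparison to 2055 with the actin covariate and 2278 to 3886 without single arrays. Shared calls numbered 1085 without the trend and 884 to 1713 without single arrays. The correlation was 0.626 without a filter, 0.878 with the filter at the 60th percentile and 0.750 to 0.846 without single arrays.

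The replicate numbers gave no clear sign of pairing: deviations from group means of same-numbered arrays correlated at -0.140, 0.020, -0.019, 0.063, 0.091 and 0.091. In a group of 2 arrays both deviations mirror each other, so the last 2 values, of upf1 with upf3, are equal by construction. The check is thus weak. With the number as a replicate block, on the 6 arrays numbered 1 and 2, calls numbered 1913 in upf1, 4380 in upf3, 343 between the mutants and 2302 pooled, and 1715 were shared. Under this replicate block list medians ended their call for NLR receptors (0.29), ribosomal proteins (-0.059) and cytochromes P450 (0.31) in upf1 and for jasmonate defence pooled (-3.86), and the autophagy median gained one pooled (0.39). Of named genes it ended the calls of UPF3 (adjusted p = 0.0543), AT2G16750 (0.127) and AT4G01410 (0.0814) in upf1, AT3G55710 (0.107) and AT3G06160 (0.083) in upf3, AT1G78110 (0.0603) between the mutants, and 15 in the pooled comparison, among them AT3G55710 (0.181), AT3G06840 (0.225), LHCB4.3 (0.183) and IAA29 (0.0556).

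List medians that crossed the threshold or reversed were, by setting, as follows. Quantile normalization gave, in upf1, 0.19 for NLR receptors, 0.19 for cytochromes P450 and a reversed 0.025 for ribosomal proteins, in upf3 -0.17 for photosynthesis genes, and pooled -3.63 for jasmonate defence, -0.060 for ribosomal proteins and -0.12 for photosynthesis genes. Centring on the 75th percentile gave 0.96 for WRKY factors in upf1, which gained a call, and -3.76 for jasmonate defence pooled. The offset of 16 gave 0.17 for cytochromes P450 in upf1. Without the trend the values were -0.078 for ribosomal proteins and 0.25 for cytochromes P450 in upf1, -0.18 for NMD factors between the mutants and -3.67 for jasmonate defence pooled. The filter at the 60th percentile, which leaves fewer members, gave 0.54, 0.94 and 0.76 for NLR receptors in upf1, in upf3 and pooled, 0.42 for autophagy genes in upf3 and -0.18 for NMD factors between the mutants, and it gained calls for WRKY factors in upf1 (1.03), cytochromes P450 pooled (0.65) and pseudogenes in upf3 (1.64), with pseudogenes reversed between the mutants (0.43 from -0.11). The actin covariate ended calls for NLR receptors (0.40 in upf1, 0.81 in upf3), cytochromes P450 (0.26), expansins (-0.24 in upf1, -0.54 in upf3, -0.31 pooled), autophagy genes in upf3 (0.26), NMD factors between the mutants (-0.14) and jasmonate defence pooled (-3.23), and gained them in upf1 for photosynthesis genes (-0.25) and WRKY factors (1.16).

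Without single arrays, the medians whose call changed ran in upf1 from 0.31 to 0.41 for NMD targets, 0.15 to 0.40 for NLR receptors, -0.17 to -0.017 for ribosomal proteins, 0.20 to 0.32 for cytochromes P450, -0.62 to -0.23 for expansins and 0.61 to 1.26 for WRKY factors. In upf3 they ran from -0.79 to -0.65 for drought and cold, -0.60 to -0.19 for light harvesting and 0.36 to 0.53 for autophagy genes. Between the mutants they ran from -0.20 to -0.12 for NMD factors, 0.062 to 0.28 for uORF genes, -0.67 to -0.12 for light harvesting, 0.16 to 0.19 for the wider NLR set and 0.28 to 0.36 for autophagy genes. Pooled they ran from -4.24 to -2.999 for jasmonate defence, 0.24 to 0.39 for cytochromes P450 and 0.19 to 0.39 for autophagy genes.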

Other observations

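Among enzyme families of specialised metabolism, fixed from the annotation before any comparison, single members changed strongly, and 0 of the 4 lists passed the test in the pooled comparison. Of 22 tested UDP-glycosyltransferase genes 6 rose and 4 fell in the pooled comparison, or 8 and 4 adjusted over the list alone (median 0.12, adjusted p = 0.506), with UGT73D1 at 5.44, UGT87A2 at 1.56, UGT78D2, of flavonol glucosylation, at 1.07 and UGT71B1 at -0.53. Of 14 cytochrome P450 genes 5 rose and 1 fell (median 0.29, adjusted p = 0.0863, but 0.0356 without wildtype replicate 2, 0.0374 without upf3 replicate 2 and 0.0467 with the filter at the 60th percentile, and 0.288 with an estimated correlation), among them CYP71B36 (2.13), CYP71B23 (1.47), CYP71B26 (1.07) and CYP71B6 (0.84). In upf1 this list passed, with 4 rises, 0 falls and a median of 0.25 (adjusted p = 0.0458, and 0.234 with an estimated correlation), but it lost that call in 5 of the 7 fits without 1 array (adjusted p from 0.0567 to 0.166), after quantile normalization (0.0604), with 16 added to every signal (0.0562), without the intensity trend (0.0847) and with the actin covariate (0.0909). Of 10 beta-glucosidase genes 4 rose and 2 fell, or 4 and 3 adjusted over the list alone (median 0.15, adjusted p = 0.489), among them BGLU25 from a signal of 127 ± 20.04 (SD, n = 3) to 287 ± 49.1 in upf1 and 316 ± 51.9 in upf3 (n = 2 each). Of 5 tau glutathione transferase genes 2 rose and 0 fell, GSTU16 (0.75) and GSTU27 (0.56, adjusted p = 0.0534 without wildtype replicate 2), with a median of -0.04, a mean of 0.01 and an adjusted p of 0.652; the median was 0.14 after quantile normalization.

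Of 14 tested expansin and xyloglucan endotransglucosylase genes, which loosen or remodel the wall, 4 fell and 0 rose in the pooled comparison (median -0.44, adjusted p = 0.00352, and 0.288 with an estimated correlation; -0.28 without wildtype replicate 1, and -0.31 with an adjusted p of 0.0625 with the actin covariate), EXPA8 from 253 ± 10.6 to 83.4 ± 2.09 in upf1 and 73.9 ± 16.7 in upf3 (pooled change -1.70, adjusted p = 2.06e-05), EXPA16 with -1.96 and XTH16 with -1.11. Of 8 autophagy genes 2 rose and 0 fell (median 0.26, adjusted p = 0.0863, but 0.0317 without wildtype replicate 3 and 0.0419 without upf1 replicate 2, and 0.598 with an estimated correlation), ATG8D by 0.70 (adjusted p = 0.0521 without wildtype replicate 1) and ATG8B by 0.60 (adjusted p = 0.0737 and 0.0666 without wildtype replicates 2 and 3, and 0.0595 and 0.0711 without upf3 replicates 1 and 2). Of 5 WRKY genes 3 rose and 0 fell, WRKY53 (1.85), WRKY47 (0.99) and WRKY6, the last by 1.05 in upf1 and 1.95 in upf3, with a median of 0.99 (adjusted p = 0.13). Of 9 bZIP genes 2 rose and 1 fell, or 3 and 1 adjusted over the list alone, with a median of 0.41 and a mean of -0.10 (adjusted p = 0.506). Of 15 serine carboxypeptidase-like genes 4 rose and 2 fell (median -0.15, adjusted p = 0.398), with scpl35 at -0.97 and SCPL27 at -1.08 and scpl46 at 0.97. Of 15 trichome birefringence-like genes 3 rose and 1 fell, or 4 and 4 adjusted over the list alone (median -0.09, adjusted p = 0.793), with TBL26 at 1.07. Of 6 tetraspanin genes 2 rose and 1 fell (median 0.09, adjusted p = 0.689), with TET8 at 1.04. Of 12 ubiquitin protease genes 2 rose and 0 fell (median 0.12, adjusted p = 0.506), and of 7 SWEET sugar transporter genes 0 rose and 1 fell, or 0 and 0 adjusted over the list alone (median -0.11, adjusted p = 0.398). The fall was that of SWEET1 (-0.46, adjusted p = 0.0483), whose call ended without wildtype replicates 1 (0.158), 2 (0.119) and 3 (0.0767) and upf3 replicates 1 (0.115) and 2 (0.118), with changes between -0.51 and -0.37. Among the other calls counted here, those of BGLU47, scpl48, TBL45, TBL23, XTH32, UBP23, UBP24 and TET3 also ended without at least 1 single array. With the actin covariate those of GSTU16 (adjusted p = 0.0631), GSTU27 (0.0762), CYP71B26 (0.0608), ATG8D (0.0727), ATG8B (0.0555) and SWEET1 (0.164) ended, while the changes were, in the same order, 0.60, 0.45, 0.75, 0.61, 0.69 and -0.44. The covariate also ended the calls of BGLU47, scpl48, TBL45, TBL23, XTH32, BZIP53, UBP23, UBP24, TET7 and TET3, with adjusted p from 0.0556 to 0.194. Those of ATG8B (adjusted p = 0.0508), SWEET1 (0.067) and TBL23 (0.0843) ended without the low-signal filter. Without the intensity trend those of SWEET1 (0.0777), scpl48 (0.0585), TBL45 (0.0514) and XTH32 (0.0611) ended. Of 2 auxin genes IAA29 fell (-2.87), a call that ended without wildtype replicate 1 (adjusted p = 0.111), 2 (0.133) or 3 (0.0614). No cysteine-rich receptor-like kinase or receptor-like protein gene of the lists was named on the array.

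Genes higher in the pooled comparison tended to lie next to each other. Of 2079 pairs of neighbouring tested genes 55 had both members higher, against a mean of 36.0 and a middle 95% of 25 to 47 in 10000 random draws of as many genes, so even spacing by chance is argued against, although the highest draw gave 61. In the fits without 1 array, a check added after this result had been seen, the number lay above at least 98.7% of the draws. The observed number was 1.53 times the mean of the draws. Leaving out probe sets that can match several transcripts took out 0 of the 55 pairs and so tested nothing, and cross-hybridisation between neighbouring copies stays open. Chosen after their values were seen, the strongest pairs were AT3G48640 (3.42) with the pseudogene AT3G48650 (3.10), and the jacalin-related lectin genes JAL33 (2.29) and JAL34 (1.77). Shared regulation of neighbouring copies is a hypothesis that was not tested.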
